A study of Tribolium castaneum with 8 samples.

How the data were processed

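The data are 4 RNA sequencing libraries of whole Tribolium castaneum, 1 each from embryos, late larvae, pupae and adults. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was selected with oligo(dT), cDNA was primed with random hexamers, and sequencing was done on an Illumina Genome Analyzer. No step that marks the strand is described, so reads of a gene and of an antisense partner cannot be told apart. Another 4 libraries, of bisulfite-treated DNA, were not analysed here. The submitters' processing notes name CASAVA 1.8.2, BSMAP 2.73 and SAMtools 0.1.19 for the series. The RNA aligner, the counting tool, the genome build and the annotation are not given in the sources used here, so no coordinates are printed.

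Per the file headers, the authors counted unique reads per gene model, and the sum of these counts equals the total in each header. The authors deposited RPKM values beside the counts, and recomputing them from the reads, the model length and the header total gave the same values to within a relative difference of 3.66e-14. The deposited coverage, the percent of each model covered by reads, was used only to compare libraries at matched read density, where medians at 20 to 40 reads per kilobase were 62.7% in the embryo, 64.0% in the larva, 63.4% in the pupa and 63.6% in the adult. Each file lists genes with at least 1 read, so an unlisted gene was taken as 0 reads. In all 14422 genes were listed in at least 1 library and 11252 in each of the 4. Of the models, 99.4% have a length that is a multiple of 3, and what the deposited length covers is not given in the sources used here. Because only unique reads were counted, members of families with near-identical copies are undercounted, and 41 models with the suffix GA may overlap others. These models and large families such as cuticle proteins, P450 enzymes and dyneins are uncertain for that reason.

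Before the data were examined, the comparisons, 25 gene lists, thresholds, the rule for naming genes and a first group of other settings were set. Libraries were compared at the 3 consecutive steps as log2 of the ratio of (RPKM + 1), a scale that understates differences of weakly expressed genes. Genes with at least 1 RPKM in at least 1 of the 2 libraries were tested, and a gene was counted as higher or lower from 2-fold on. No p-value was computed, because each stage has 1 library and genes are not replicates. Ratios of named genes are ratios of RPKM without the added 1, with exact conditional binomial 95% intervals on the reads. For a gene with 0 reads in 1 library the bound used a floor of 3 reads in that library. Stage-restricted genes had at least 5 RPKM in 1 library and (RPKM + 1) at least 4 times that of each other library. Spearman correlations were computed across genes for all 6 pairs.

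The lists were matched by name patterns on the protein descriptions in the files: cuticle proteins, chitin synthesis and turnover, cuticle tanning, chemoreceptors, odorant-binding and chemosensory proteins, digestive enzymes, storage and yolk proteins, ovary and germline, sperm and cilia, cytosolic ribosomal proteins, DNA replication and cell cycle, muscle sarcomere, homeobox and patterning, ecdysone and juvenile hormone, cytochrome P450, glutathione S-transferases, antimicrobial and immune recognition, heat shock proteins, DNA methylation machinery, histone modification, oxidative phosphorylation, neuronal, photoreception, autophagy and apoptosis, and lipid synthesis. Together they hold 1002 genes. A list's median was placed among 10000 random lists of the same size, drawn with a fixed seed from 20 bins of mean log2(RPKM + 1), and lists with fewer than 5 tested genes were given gene by gene. Only 4079 genes carry an informative name, so lists are incomplete. Some members were matched by a word in their name and have another function.

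Genes named in the text were chosen by the fixed rule. For each step these were the 12 largest differences in each direction among informatively named genes with at least 10 RPKM in 1 of the libraries, with at most 3 per list. Each list's most changed and most abundant members, all detected methylation and hormone genes, the 8 most abundant restricted genes per stage and the 5 most abundant genes per library could also be named. Arrestin 1 was named because its list is given gene by gene.

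The settings chosen then were a pseudocount of 0.1, no filter and a filter of 5 RPKM, median-ratio rescaling, leaving the 20 most abundant genes of each library (53 genes in all) out of the totals, a 4-fold threshold, counting only genes whose interval lies beyond 2-fold, leaving out models shorter than 300 bases, and other margins for restricted genes. TPM scaling, thinning, names from the KEGG field, lists without unrelated names and list medians with 0 reads at the floor were added after seeing the data. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

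The steps were tested on simulated data, with Poisson reads for the real genes and 200 changed genes. The changed genes were drawn only from those with a mean of at least 5 RPKM over the libraries of the step. Recovery of changes in weaker genes was therefore not tested. For embryo to larva, with 12022 genes tested, 99% of 3-fold and 100% of 8-fold changes were counted, and 380 of 11822 unchanged genes (3.21%). For larva to pupa, with 12072 genes tested, these values were 94%, 100% and 381 of 11872 (3.21%), and for pupa to adult, with 12544 genes tested, 97%, 100% and 460 of 12344 (3.73%). Counting only intervals beyond 2-fold left 1, 0 and 1 unchanged genes and counted 70%, 72% and 73% of the 3-fold changes. Among unchanged tested genes with reads in both libraries, intervals held the true ratio for 96.1%, 96.2% and 96.1%.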

Results

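The series followed whole bodies of the red flour beetle Tribolium castaneum, a stored-grain pest with complete metamorphosis, in the laboratory strain GA-1. Polyadenylated RNA was sequenced from embryos, late larvae, pupae and adults, with 1 library per stage. The embryos, pupae and adults were 3 days old and the larvae about 20 days old. A further 4 libraries, bisulfite libraries for DNA methylation, were not analysed here. The RNA libraries held 3.24 M unique reads in genes for the embryo, 3.58 M for the larva, 3.67 M for the pupa and 3.09 M for the adult. The median listed gene had 90 reads in the embryo library, 81 in the larval, 86 in the pupal and 71 in the adult library. With 1 library per stage no difference has a replicate check, so values describe these libraries and not the spread between animals. All intervals are 95% counting intervals and cover counting error only.

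The larval library was led by hexamerins, the storage proteins that insects build up before metamorphosis. Hexamerin 1B (TC005377) took 4.69% of larval reads, arylphorin (TC005376) 3.53% and hexamerin 2 (TC006769) 3.16%. They were followed in the larval library by proteins of unknown function, TC013741 with 2.42% and TC012207 with 1.88%. In the adult library, TC030701, of unknown function, took 2.40% of reads, TC005924 1.30%, the giant muscle-specific protein 300 (TC010669) 1.08%, myosin light chain (TC011769) 0.832% and TC000933 0.763%. In the pupal library, TC006664 took 3.34%, TC030701 0.853%, TC003047 0.497%, TC005924 0.430% and elongation factor 1-alpha (TC001880), which brings tRNAs to the ribosome, 0.418%. The embryo library had the flattest distribution of the 4 libraries, with TC030701 at 1.13%, TC006664 at 0.428%, the osiris-like protein TC011661 at 0.352%, TC003097 at 0.351% and elongation factor 1-alpha at 0.343%. The 20 most abundant genes together took 6.65% of embryo reads, 21.7% of larval, 10.2% of pupal and 14.0% of adult reads. At least 1 RPKM was reached by 11109 genes in the embryo library, 11136 in the larval, 11468 in the pupal and 12215 in the adult library. After thinning to the total of the adult library the counts were 11124, 11147 and 11464 for embryo, larva and pupa.

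Among the 6 pairs of libraries, the embryo and pupal libraries were the most alike, with a Spearman correlation of 0.842 across genes. The larval and pupal libraries followed at 0.743 and the pupal and adult libraries at 0.723. The adult library was less like the larval library, at 0.644, and the embryo library less like the larval, at 0.636, and the adult, at 0.608. These correlations are across genes, which are not replicates.

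The first consecutive comparison set the larval library against the embryo library. The 3 hexamerins stood far higher in the larva. Hexamerin 2 (TC006769) was at 7.20 RPKM in the embryo library and 15056 in the larval library, a ratio of 2090.5 (1581 to 2826), and hexamerin 1B (TC005377) differed 1813-fold (1464 to 2273). Arylphorin (TC005376) differed 1528-fold (1219 to 1943). Of the 10 storage and yolk proteins, 9 were at least 2-fold higher in the larval library and 0 lower. Digestive proteases were also higher. Cathepsin L (TC011000), a digestive cysteine protease, stood at 0.937 and 1231 RPKM, a ratio of 1314 (449 to 6373) resting on 3 embryo reads.

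Digestive enzymes were higher in the larval library in 37 of 46 genes and lower in 6. Chymotrypsin-like proteinase 5A (TC013709) went from 3 embryo reads to 1420 RPKM, a ratio of 1198 (410 to 5810), whereas carboxypeptidase A (TC005500) was 19.4-fold lower (16.3 to 23.2). Serine protease P166 (TC015780) had 0 embryo reads and was at least 568-fold higher. In chitin synthesis and turnover, 25 of 35 genes were higher and 1 lower. Peritrophic matrix protein 2-B (TC003275), of the chitinous lining of the gut, stood at 0.584 RPKM from 1 embryo read and 1864 RPKM in the larva, a ratio of 3194 (573 to 126190). Cuticle proteins were higher in 53 of 70 genes and lower in 6. The pupal cuticle protein 78E (TC013136) was at 2.43 and 3877 RPKM, a ratio of 1597 (546 to 7748.5) with 3 embryo reads, and Pupal cuticle protein TC014500 was at 2.03, from 2 reads, and 1452 RPKM. Cuticular protein 66D (TC008767) went the other way, with 143 RPKM in the embryo and 0 larval reads, at least 119-fold lower.

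Detoxification and immune genes were higher in the larva as well. Cytochrome P450 enzymes were higher in 86 of 113 genes and lower in 5. P450 9F2 (TC006445) was at 11.2 and 2106 RPKM, 188-fold apart (144 to 249), and a family 4 P450 (TC012502) was 258-fold higher (148 to 499.8). Cytochrome P450 15A1 (TC002551), an enzyme of juvenile hormone synthesis, was instead 22.4-fold lower (16.4 to 31.3). Glutathione S-transferases were higher in 11 of 19 genes and lower in 4, with transferase E6 (TC004942) at 4.69 and 391 RPKM. All 15 antimicrobial and immune recognition genes were higher, among them the thaumatin-like proteins TC000515 and TC011564, at least 387-fold and 335-fold above 0 embryo reads. Odorant-binding and chemosensory proteins, small carriers of hydrophobic ligands, were higher in 31 of 48 genes and lower in 6. Chemosensory protein 20 (TC015902) was 981-fold higher (420 to 3021), while chemosensory protein 2 (TC003085) stood at 231 RPKM in the embryo and had 1 larval read, 304-fold lower (54.2 to 12061). Lipid synthesis genes were higher in 5 of 7 and lower in 0, with Z9 acyl-CoA desaturase A (TC011471) 111-fold higher (47.4 to 344). The list of cuticle tanning genes had 5 of 7 higher and 1 lower. Of its members, laccase 1 (TC000821) was 24.9-fold higher (10.4 to 77.8). The 1 lower was an Enhancer of yellow 2 transcription factor homolog (TC013873), matched by a word in its name.

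Homeobox and neuronal genes were higher in the embryo library. Homeobox and patterning genes were at least 2-fold lower in the larva in 31 of 34 cases, with the LIM homeobox gene TC001291 at 36.7 and 1.68 RPKM, 21.9-fold lower (10.3 to 55.5). Neuronal genes were lower in 23 of 31 cases. The nicotinic acetylcholine receptor beta gene TC001432 was 28.2-fold lower (15.9 to 55.2), and Syntaxin 1A (TC011694), a synaptic vesicle fusion protein, stood at 311 and 124 RPKM. Outside the lists, 4 genes of the Osiris family of insect proteins were among the 12 named genes with the largest differences downward. The osiris-like protein TC011661 was 25.3-fold lower (23.1 to 27.7), Osiris TC011658 46.2-fold (40.1 to 53.5), Osiris TC012679 79.5-fold (57.8 to 113) and osiris 16 (TC012680) 62.6-fold (24.1 to 232). Proteoglycan 4 (TC015076) was 130-fold lower (62.7 to 324), lactoylglutathione lyase (TC011665) 38.8-fold (32.6 to 46.6), and the Olig family transcription factor TC014712 stood at 100.0 RPKM in the embryo and had 3 larval reads, 94.4-fold lower (32.0 to 461).

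Of 12179 genes tested, 2269 were at least 2-fold higher and 4169 at least 2-fold lower in the larval library, 35.2% higher among those counted. This balance depended on the scaling, with 3026 higher and 2002 lower after median-ratio rescaling and 2602 and 3136 with the 20 most abundant genes of each library left out of the totals. The larger differences lay on the other side, with 557 genes at least 16-fold higher and 97 at least 16-fold lower. The median of all genes tested was -0.62 on the log2 scale, so list medians are given relative to it. Antimicrobial and immune recognition genes lay 5.24 above it, storage and yolk proteins 4.01, digestive enzymes 3.80, cuticle proteins 2.85, P450 enzymes 2.84, lipid synthesis 2.70, chitin genes 2.69, glutathione S-transferases 2.18, odorant-binding and chemosensory proteins 2.16, and tanning genes 1.98. The 33 ecdysone and juvenile hormone genes lay 1.42 above it and the 9 muscle sarcomere genes 1.10 above. Neuronal genes lay at -1.72 and homeobox genes at -1.57. Each of these lists fell outside the central 95% of 10000 random lists of equal size and matched expression, at percentiles from 99.185 for muscle genes to 100, or at 0, as a description of these libraries. The chitin median of 2.07 was 5.25 over the 22 genes left without unrelated names. Over genes named in either name field the tanning median of 1.35 was 0.17 (19 genes, 8 higher and 5 lower), the lipid synthesis median of 2.08 was 0.72 (58, with 28 higher and 13 lower), the transferase median of 1.56 was 0.88 and the muscle median of 0.47 was 0.15, each still above the random range.

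Other lists stood closer to the median of all genes. Cytosolic ribosomal proteins were lower in 49 of 59 genes, with a median of -1.11 and a percentile of 0, but 8 genes passed 2-fold with the 20 most abundant genes left out and 0 after median-ratio rescaling, where the median was -0.45. Ribosomal protein S15Ae (TC012128) stood at 5830 and 2838 RPKM and L35e (TC014007) at 1310 and 436. Oxidative phosphorylation genes had a median of -0.16, which was 0.47 above that of all genes at percentile 98.8 and changed sign under median-ratio rescaling, to 0.50, and with abundant genes left out, to 0.12. Heat shock proteins had a median of 0.18 at percentile 98.5, but -0.18 and 94.25, within the random range, for the 34 named in either name field, with small heat shock protein 21 (TC006593) 58.2-fold higher (36.7 to 98.6) and its namesake TC006793 4.78-fold lower (2.95 to 8.09). The remaining lists of at least 5 genes lay within the random range. Histone modification genes had a median of -1.11 (percentile 5.89), though the 68 named in either name field stood at -0.92 (0.77), below that range. Chemoreceptors had a median of -0.87 (35.3), sperm and cilia genes -0.69 (41.2) and autophagy and apoptosis genes -0.66 (49.7). DNA replication and cell cycle genes stood at -0.64 (50.5) and ovary and germline genes at -0.58 (51.2), 0.04 and 0.07 after median-ratio rescaling. Of 256 chemoreceptor genes in the files, 22 passed the filter on low values. The photoreception and DNA methylation lists, with 3 genes each, were too small for a random range. Of the photoreception genes 1 was higher and 1 lower. The wider DNA methylation list, matched in either name field, held 27 genes, of which 11 were tested. It lay below the random range, with a median of -1.44 (percentile 0.82). Unrelated names were not removed from this wider list.

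**Figure D1:**
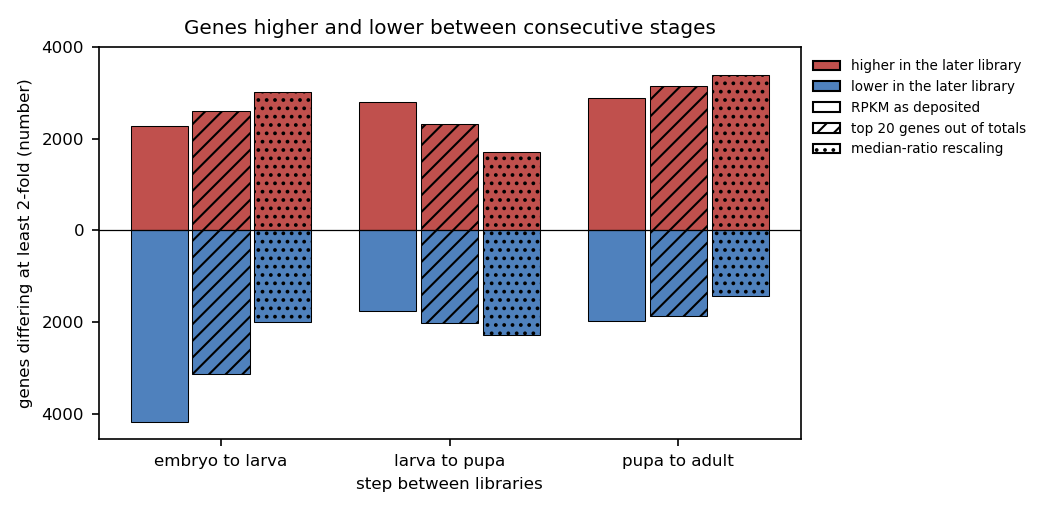
Number of genes at least 2-fold higher (red) or lower (blue) in the later library at each consecutive step, by scaling; each bar compares 1 library with 1 library. The embryo to larva step had 2269 genes higher and 4169 lower as deposited but 3026 and 2002 after median-ratio rescaling, and the larva to pupa balance turned from 2792 and 1748 to 1712 and 2283.

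The next comparison set the pupal library against the larval library. Of 10 storage and yolk proteins, 5 were at least 2-fold lower in the pupal library and 1 was higher. Hexamerin 2 (TC006769) was 1841-fold lower (1439 to 2396), arylphorin (TC005376) 1202-fold (995 to 1465) and hexamerin 1B (TC005377) 359-fold (328 to 394). The 1 higher was hexamerin 5 (TC006515), at 86.0 RPKM in the larva and 1370.4 in the pupa, 15.9-fold higher (14.7 to 17.3). Digestive enzymes were lower in 30 of 46 genes and higher in 5. Chymotrypsin-like proteinase 5A (TC013709) had 2 pupal reads, 2034-fold lower (563 to 16800), and cathepsin L was 744-fold lower (341 to 2028) for TC011000 and 814-fold (317 to 2988) for TC009365. Carboxypeptidase A TC005905, in contrast, was 12.7-fold higher (11.2 to 14.4).

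Cuticle proteins were lower in the pupal library in 49 of 71 genes and higher in 9. Cuticle protein 78E (TC013136) was 1356-fold lower (529 to 4979.9), whereas cuticle protein TC002434 had 0 larval reads and was at least 31.2-fold higher. In chitin synthesis and turnover 21 of 35 genes were lower and 4 higher, with chitinase 8 (TC009624) 1575-fold lower (539 to 7640.2) on 3 pupal reads and the peritrophin-like cuticular protein 3-A2 (TC011141) 12.6-fold higher (9.06 to 17.9). P450 enzymes were lower in 67 of 113 genes and higher in 10, led by P450 9F2 (TC006445), 585-fold lower (378.4 to 957.7). Glutathione S-transferases were lower in 8 of 19 genes and higher in 3, and lipid synthesis genes in 4 and 0 of 7, with desaturase A (TC011471) 105-fold lower (47.9 to 287). Antimicrobial and immune recognition genes were lower in 6 of 15, with the thaumatin-like TC000515 219-fold lower (100.3 to 598), and higher in 1, the thaumatin-like TC000516, at 5.01 and 34.1 RPKM. Odorant-binding and chemosensory proteins were lower in 27 of 46 and higher in 7, with odorant binding protein C13 (TC030448) 484-fold lower (165 to 2348) on 3 pupal reads and C02 (TC010067) 6.68-fold higher (6.03 to 7.40). Muscle protein 20 (TC007135) was 17.1-fold lower (14.5 to 20.4), and 4 of 9 genes of the sarcomere list were lower and 1 higher, the calponin-homology protein TC010993, at 2.54 and 33.4 RPKM. Without unrelated names, TC010993 among them, 3 of 7 were lower and 0 higher.

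Among the named genes higher in the pupa, Osiris TC012679 stood at 13.7 and 1608 RPKM, 117-fold higher (85.2 to 166), and osiris 16 (TC012680) was 51.9-fold higher (20.0 to 192). The nuclear receptor E78 (TC003935) was 33.0-fold higher (20.1 to 58.1), the transcriptional repressor Blimp-1 (TC014741) 36.8-fold (25.7 to 54.3) and the segment polarity homeodomain protein invected (TC016368) 26.7-fold (19.3 to 37.95). A wingless-type gene (TC002386) was 20.2-fold higher (7.60 to 75.9). Beta-2 tubulin (TC009035) was at 1.45 and 90.1 RPKM, 62.0-fold higher (29.9 to 155), and the actin-bundling protein villin (TC013108) 26.2-fold higher (19.9 to 35.2). A carboxypeptidase A (TC005904) outside the digestive list was 72.5-fold higher (43.0 to 133). Neuronal genes were higher in 13 of 31 cases and lower in 0, or in 7 and 1 after median-ratio rescaling and 10 and 1 with abundant genes left out. Genes of sperm and cilia were higher in 11 of 17 cases and lower in 1. Tektin (TC005997), a structural protein of axonemes, had 1 larval read and 8.38 RPKM in the pupa, a ratio of 44.8 (7.65 to 1807).

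Of 12280 genes tested, 2792 were at least 2-fold higher and 1748 lower in the pupal library, 61.5% higher among those counted, against 1712 and 2283, or 42.9%, after median-ratio rescaling. Beyond 16-fold, 88 genes were higher and 399 lower. The median of all genes was 0.43. Relative to it, cuticle proteins lay at -2.58, lipid synthesis genes at -2.49, digestive enzymes at -2.49, chitin genes at -2.33, P450 enzymes at -1.79, odorant-binding and chemosensory proteins at -1.71, storage and yolk proteins at -1.51, ecdysone and juvenile hormone genes at -1.17, glutathione S-transferases at -1.11, muscle genes at -1.01 and immune genes at -0.86, each at a percentile of 0.5 or below. Oxidative phosphorylation genes, with a median of -0.22, lay at -0.65 and percentile 0, but their mean was 0.05 and 5 of 52 were at least 2-fold higher and 1 lower, or 5 and 6 after median-ratio rescaling. Of 9 histone modification genes 2 were higher and 0 lower as deposited, and 0 higher after median-ratio rescaling or with abundant genes left out. They lay 0.54 above the median of all genes (percentile 98.6) and neuronal genes 0.52 (99.755), and sperm and cilia genes had a median of 1.43 (99.97). The chitin median of -1.90 was -4.70 over 22 genes without unrelated names and -0.91 over the 74 named in either name field, of which 9 were higher and 36 lower. Over the 60 lipid synthesis genes named in either field the median of -2.06 was -0.07, with 16 higher and 20 lower. The odorant-binding and chemosensory median, -1.27, was -0.05 when genes with 0 reads were set at the 3-read floor, and the muscle median of -0.58 was 0.19 for the 40 genes with a muscle name in either name field, at percentile 8.25 and so within the random range.

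The other lists of at least 5 genes lay within the random range at this step. Of the 3 photoreception genes, too few for a random range, 2 were higher and 0 lower, or 1 and 0 after median-ratio rescaling. The 13 photoreception genes named in either name field lay above the random range, with a median of 1.30 (percentile 99.91), 8 higher and 0 lower. Homeobox and patterning genes had a median of 0.65 (percentile 84.3), tanning genes 0.71 (80.7) and autophagy and apoptosis genes 0.50 (57.8). Cytosolic ribosomal proteins (0.30, percentile 60.8), chemoreceptors (0.41, 61.8), ovary and germline genes (0.39, 49.0) and DNA replication genes (0.34, 17.9) took the opposite sign after median-ratio rescaling, at -0.16, -0.02, -0.06 and -0.10. Heat shock proteins stood at 0.11 (8.01), at -0.26 after median-ratio rescaling and at -0.03 with abundant genes left out.

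The last step set the adult library against the pupal library. Odorant-binding and chemosensory proteins, oxidative phosphorylation genes and muscle genes were higher in the adult. Chemosensory protein 11 (TC008681) stood at 46.1 RPKM in the pupa and 16387 in the adult, 356-fold higher (279 to 461), and odorant binding protein C17 (TC008162) had 1 pupal read and 901 adult RPKM, a ratio of 1291 (231 to 51051). Odorant-binding and chemosensory proteins were higher in 46 of 58 genes and lower in 8, among them C01 (TC010066), at 9696 and 283 RPKM, 34.3-fold lower (30.8 to 38.3). Of 52 oxidative phosphorylation genes, 43 were higher and 0 lower, with the ATP synthase beta subunit (TC015322) 2.22-fold higher (2.14 to 2.30).

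Muscle sarcomere genes were higher in 7 of 9 cases and lower in 0. Myosin light chain (TC011769) was at 1846 and 9665 RPKM, 5.23-fold higher (5.09 to 5.39), and troponin C (TC012704) at 649 and 779. Genes of sperm and cilia were higher in 10 of 17 cases, with an axonemal inner arm dynein light chain (TC011080) 13.2-fold higher (6.44 to 31.6), and lower in 1, Spermidine Synthase (TC015179), an enzyme of polyamine synthesis matched by its name. The 3 photoreception genes were higher, rhodopsin (TC013765) 40.9-fold (24.1 to 75.4), arrestin 2 (TC009551) 4.63-fold (4.06 to 5.30) and arrestin 1 (TC013804) from 9.36 to 49.7 RPKM. Cuticle proteins were higher in 34 of 61 genes and lower in 10. Cuticle protein CP6 (TC013135) was 317-fold higher (177 to 636), while Cuticular protein 66D (TC002908) stood at 178 RPKM in the pupa and had 3 adult reads, 178-fold lower (60.5 to 863). Chitin genes were higher in 22 of 36 cases and lower in 4, with chitinase 8 (TC009624) 132.5-fold higher (45.0 to 646) on 3 pupal reads.

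Some digestive and P450 genes that stood higher in the larval library than in the pupal one were also higher in the adult library than in the pupal one. Among genes reaching 1 RPKM in any library, 35 of 48 digestive enzymes were highest in the larval library and 6 in the adult. For P450 enzymes these were 60 and 43 of 123. P450 9F2 (TC006445) stood at 3.60 and 1306 RPKM, 363-fold higher (235 to 594), and P450 enzymes were higher in 68 of 120 genes and lower in 22. Digestive enzymes were higher in 19 of 39 genes and lower in 11. Cathepsin L (TC011000) was 90.5-fold higher (41.2 to 248) and a trypsin-like protease (TC004635) 141-fold lower (85.6 to 253). Glutathione S-transferases were higher in 11 of 19 genes and lower in 3, and lipid synthesis genes in 5 of 8 and lower in 1. Outside the lists, the ADFb-like proteins TC009959 and TC009955 were 630-fold (332 to 1379.5) and 398-fold (193 to 992) higher, and serine protease H88 (TC008930), with 0 pupal reads, at least 192-fold. Lower in the adult library were the Osiris gene TC012679, 349-fold (195 to 700.1), Osiris TC011658, 128-fold (77.4 to 229), hexamerin 5 (TC006515), 172-fold (131 to 230.2), hexamerin 4 (TC005375), 139-fold (98.2 to 203), and glucose dehydrogenase (TC015723), 61.5-fold (45.7 to 84.8).

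Of 12713 genes tested, 2899 were at least 2-fold higher and 1984 lower in the adult library, 59.4% higher among those counted, against 3398 and 1428, or 70.4%, after median-ratio rescaling. Beyond 16-fold, 282 were higher and 165 lower. The median of all genes was -0.09. Relative to it, odorant-binding and chemosensory proteins lay 3.43 above, muscle genes 2.48, sperm and cilia genes 2.21, cuticle proteins 1.64, chitin genes 1.63, oxidative phosphorylation genes 1.42, lipid synthesis genes 1.33, P450 enzymes 1.31, glutathione S-transferases 1.23, digestive enzymes 0.95 and heat shock proteins 0.74, each at a percentile of 98.4 or higher. Storage and yolk proteins lay at -0.88 (percentile 1.58), histone modification genes at -0.81 (2.015), immune genes at -0.72 (0.44) and homeobox genes at -0.31 (1.54). Without unrelated names, 26 homeobox genes lay at -0.11 (6.08) and 19 heat shock genes at 0.82 (95.4), both within the random range, whereas the 107 homeobox and 36 heat shock genes named in either name field lay outside it, at -0.45 (0) and 0.63 (99.3). The 70 histone modification genes named in either field lay within it, at -0.26 (8.61). Defensin 1 (TC012469), an antimicrobial peptide, stood at 14.0 RPKM in the pupa and had 1 adult read. When genes named in either name field were taken, the muscle median of 2.39 was 0.50, the lipid synthesis median of 1.23 was -0.59, the chitin median of 1.53 was 1.01, the transferase median of 1.14 was 0.72, the immune median of -0.82 was -1.77 and the photoreception median of 2.29 was 0.23. The 60 lipid synthesis genes of that wider list, 21 higher and 22 lower, thus lay below the random range (percentile 0), opposite to the 8 of the fixed list.

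Lists within the random range at this step were ecdysone and juvenile hormone genes with a median of 0.50 (percentile 89.5), chemoreceptors at 0.78 (24.2), tanning genes at 0.74 (93.4), autophagy and apoptosis genes at -0.75 (3.01) and cytosolic ribosomal proteins at -0.28 (76.1). Ovary and germline genes stood at -0.20 (47.7) and at 0.08 after median-ratio rescaling. DNA replication genes stood at 0.03 (91.2) and at -0.00484 with TPM scaling. Neuronal genes stood at -0.05 (40.3), at 0.13 after median-ratio rescaling and at 0.00148 with abundant genes left out. Arylalkylamine N-acetyltransferase (TC001154), a tanning enzyme, was 20.6-fold higher in the adult library (14.9 to 29.0), and caspase-1 (TC003841), a cell death protease, 3.21-fold lower (2.23 to 4.71).

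**Figure D2:**
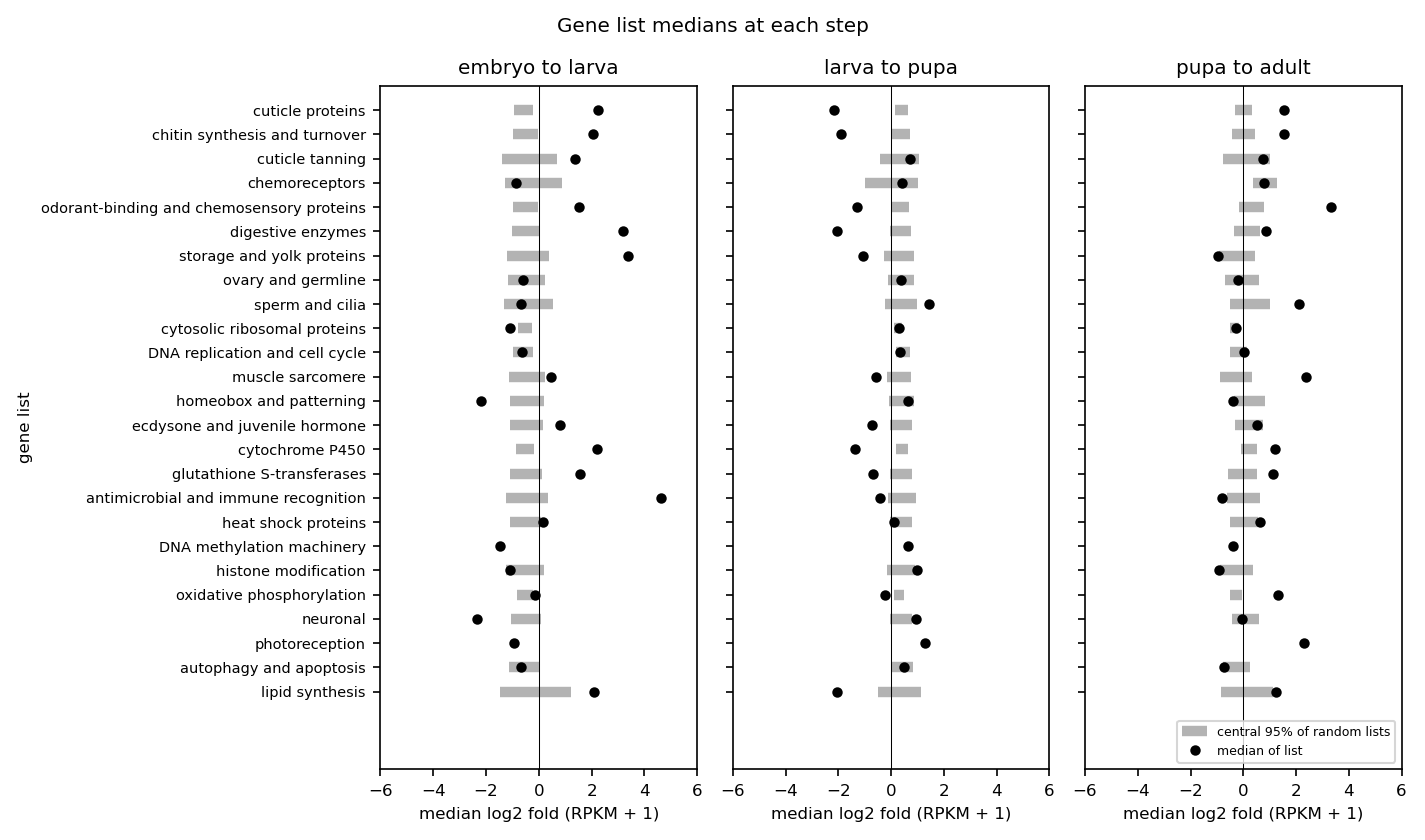
Median log2 fold of (RPKM + 1) of each gene list (points) at the 3 consecutive steps, with the central 95% of 10000 matched random lists (grey bars, drawn for lists of at least 5 genes). The immune gene median was 4.62 from embryo to larva and the odorant-binding and chemosensory median 3.33 from pupa to adult; the oxidative phosphorylation median of -0.16 from embryo to larva changed sign, to 0.50, after median-ratio rescaling.

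Genes were counted as restricted to a stage when they had at least 5 RPKM in its library and at least 4 times the value of each other library. The adult library had 873 such genes, holding 18.9% of its reads, and the larval library 459, holding 25.7%. The embryo library had 265 (3.06%) and the pupal library 66 (6.31%). Of the pupal share, TC006664, of unknown function, alone took 3.34% of pupal reads. Larval genes included hexamerin 1B (TC005377) at 20317 RPKM, chemosensory protein 10 (TC008682) at 3273, 21 cuticle proteins, 19 digestive enzymes and 14 P450 enzymes. Adult genes included chemosensory protein 11 (TC008681), odorant binding protein C11 (TC011410) at 9274 RPKM, cytochrome c proximal (TC005841) of the respiratory chain at 1866, immune-related Hdd11 (TC013059) at 2144, 25 odorant-binding and chemosensory proteins and 8 sperm and cilia genes. Embryo genes included osiris 7 (TC011660) at 2544 RPKM, the Wnt pathway regulator naked cuticle (TC001637) at 207, 8 homeobox genes and 5 neuronal genes. Pupal genes included midline fasciclin (TC012903), a cell adhesion protein, at 857 RPKM, a phosphatidylethanolamine binding protein (TC013412) at 416 and serine protease P141 (TC013415) at 249.9. After median-ratio rescaling the embryo count was 159, and with a 2-fold margin the counts were 968 for embryo, 836 for larva, 246 for pupa and 1351 for adult.

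The labels pair these libraries with DNA methylation libraries, so the genes of the methylation machinery are given one by one. As deposited, each had its highest value in the embryo library, but for DNA methyltransferase 1 the embryo and larval values lay close together after median-ratio rescaling. The methyl-CpG binding protein (TC003775), a reader of methylated DNA, stood at 93.0 RPKM in the embryo, 26.0 in the larva, 41.5 in the pupa and 29.0 in the adult, 3.58-fold lower in the larva than in the embryo (2.64 to 4.92). Its log2 fold at that step was -1.80 as deposited and -1.16 after median-ratio rescaling. DNA methyltransferase 1 (TC013587), the maintenance enzyme, stood at 29.5, 19.8, 21.5 and 16.8 RPKM, 1.49-fold lower in the larva (1.31 to 1.70). Its log2 fold from embryo to larva was -0.55 as deposited and 0.08 after median-ratio rescaling. DNA methyltransferase 2 (TC005511), which methylates tRNA, stood at 25.2, 8.47, 18.7 and 14.1 RPKM and was 2.21-fold higher in the pupa than in the larva (1.42 to 3.51). Its log2 fold from larva to pupa was 1.06 as deposited but below 2-fold at 0.64 after median-ratio rescaling and 0.88 with abundant genes left out. From pupa to adult the median of the 3 genes was -0.39, and it was -0.13 after median-ratio rescaling.

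Among ecdysone and juvenile hormone genes, 16 of 33 were higher and 2 lower in the larva than in the embryo, and 13 of 34 were lower and 3 higher in the pupa than in the larva. Juvenile hormone epoxide hydrolase (TC003438), which degrades the hormone, stood at 0.890 RPKM in the embryo and 56.7 in the larva, 63.7-fold higher (24.6 to 235.5). Juvenile hormone-inducible protein TC009655 had 0 embryo reads, 21.7 RPKM in the larva, 0 pupal reads and 11.8 RPKM in the adult. The ecdysone-responsive transcription factor broad-complex (TC005476) stood at 9.74, 41.0, 3.91 and 1.86 RPKM over the 4 stages, and ftz transcription factor 1 (TC002550) at 30.5, 62.8, 4.16 and 39.8. Bursicon beta (TC013831), part of the hormone that hardens new cuticle, stood at 15.1, 3.43, 10.7 and 0.794 RPKM, the adult value from 1 read. The ecdysone receptor isoform A model TC012112-GA stayed below 3 RPKM in each library, and 2 other models carry the receptor's name, with reads shared between such models not counted.

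**Figure D3:**
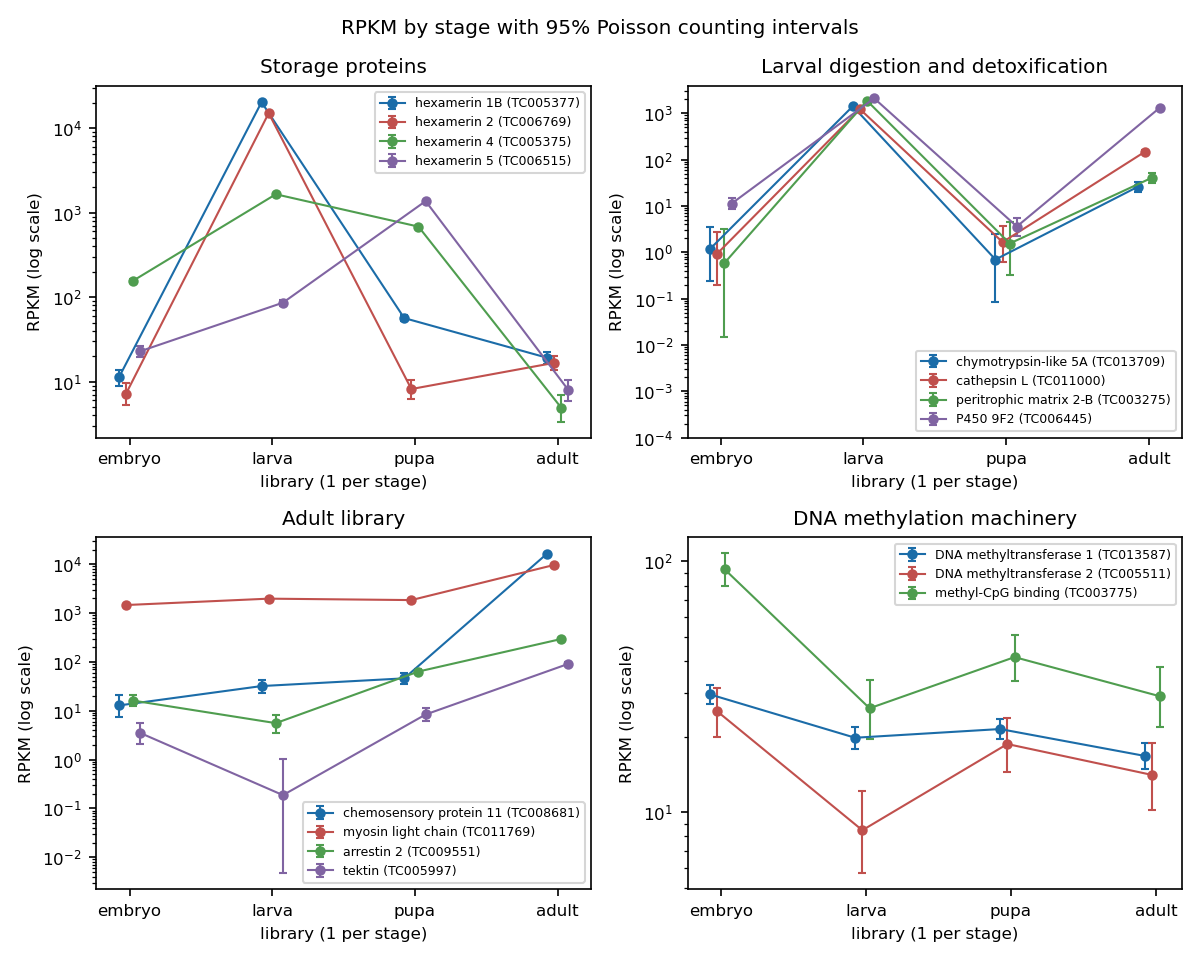
RPKM (log axis) of named genes in the embryo, larval, pupal and adult libraries, 1 library per stage, with 95% Poisson counting intervals. Hexamerin 1B reached 20317 RPKM in the larva, and chemosensory protein 11 reached 16387 in the adult. The 3 methylation genes were highest in the embryo as deposited. For DNA methyltransferase 1 the embryo and larval values lay close together after median-ratio rescaling, at a log2 fold of 0.08.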

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

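Alternatives added after seeing the data were TPM scaling, thinning, names from the KEGG field, lists without unrelated names, 0 reads at the floor, and the filters for the 3 correlations of non-consecutive stages. No paired analysis was possible because each stage has 1 library. For the step counts 48 of 60 alternative values lay within 1.5 times the reported count, and for restricted genes 27 of 32. The step counts without a filter on low values could not differ, because values below 1 RPKM never lie 2-fold apart as (RPKM + 1). Of list medians, 631 of 675 stayed within the 95% order-statistic interval of the median over the list's members. In lists of 3 genes this interval is only the range of the members and covers less than 95%. Some of the 675 alternatives could not move, because several lists have the same members with KEGG names or without unrelated names. The order-statistic interval was adopted after the values had been seen, in place of the standard deviation of the members, which had marked fewer medians as moved. For single named genes 895 of 1036 stayed within counting error. Of those at least 2-fold apart 0 changed sign, but a change of sign was not possible there. A pseudocount cannot change a sign, and each rescaling shifted a step by less than 2-fold. Depth limits genes near 1 RPKM, where few reads stand behind a value. Unless stated, the cause was not tested.

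Median-ratio rescaling gave 2002 genes lower from embryo to larva, 1712 higher from larva to pupa and 159 embryo-restricted genes. A 4-fold threshold, which counts fewer genes by construction, gave 1449 higher and 1175 lower from embryo to larva, 720 and 973 from larva to pupa, and 1491 and 582 from pupa to adult. Counting intervals beyond 2-fold, stricter by construction, gave 2298 lower from embryo to larva, 1295 higher from larva to pupa, and 1888 higher and 1008 lower from pupa to adult. With a 2-fold margin, looser by construction, restricted genes numbered 968 in the embryo, 836 in the larva, 246 in the pupa and 1351 in the adult.

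Without a filter on low values the Spearman correlations were 0.703 for embryo and larva, 0.868 for embryo and pupa, 0.666 for embryo and adult, 0.786 for larva and pupa, 0.701 for larva and adult and 0.774 for pupa and adult. With at least 5 RPKM they were, in the same order, 0.540, 0.793, 0.506, 0.671, 0.544 and 0.611. Thinned reads gave 0.742 for larva and pupa. Embryo and pupa were the highest pair under each of these filters.

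Of the list medians 22 of 675 changed sign, 6 of them in lists outside the random range. Heat shock proteins from embryo to larva stood at -0.0330 with at least 5 RPKM and at -0.18 with KEGG names. Oxidative phosphorylation from embryo to larva stood at 0.50 after median-ratio rescaling and 0.12 with abundant genes left out. With KEGG names, muscle genes from larva to pupa stood at 0.19 and lipid synthesis from pupa to adult at -0.59. Of lists within the random range, 5 changed sign and left the order-statistic interval. After median-ratio rescaling DNA replication stood at 0.0425 from embryo to larva and -0.10 from larva to pupa, ribosomal proteins at -0.16 from larva to pupa and neuronal genes at 0.13 from pupa to adult. With at least 5 RPKM chemoreceptors stood at -0.29 from pupa to adult, over 6 genes. In the other 11 the median changed sign within its interval.

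Other medians kept their sign and left the interval. After median-ratio rescaling, from embryo to larva, ribosomal proteins stood at -0.45 and autophagy and apoptosis at -0.0153. From larva to pupa, hormone genes stood at -1.15, oxidative phosphorylation at -0.67 and neuronal genes at 0.52. From pupa to adult, ribosomal proteins stood at -0.00828, DNA replication at 0.29, DNA methylation genes at -0.13 and oxidative phosphorylation at 1.60. With abundant genes left out, ribosomal proteins stood at -0.83, 0.0918 and -0.21 at the 3 steps, oxidative phosphorylation from larva to pupa at -0.42 and DNA methylation genes from pupa to adult at -0.32. TPM scaling gave ribosomal proteins 0.34 from larva to pupa.

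A pseudocount of 0.1, which widens differences of weak genes by construction, gave cuticle proteins 3.52, odorant-binding and chemosensory proteins 3.398 and P450 enzymes 3.36 from embryo to larva. It gave odorant-binding and chemosensory proteins -2.67 from larva to pupa and 5.06 from pupa to adult, and chemoreceptors 1.49 and P450 enzymes 1.76 from pupa to adult. With at least 5 RPKM, chemoreceptors stood at -1.87 from embryo to larva and 1.33 from larva to pupa, over 8 and 4 genes, and odorant-binding and chemosensory proteins at 2.98 from embryo to larva. With 0 reads at the floor, P450 enzymes stood at 3.03 from embryo to larva and 1.61 from pupa to adult, odorant-binding and chemosensory proteins at -0.0473 from larva to pupa and sperm and cilia genes at 2.57 from pupa to adult. Without unrelated names, chitin genes stood at 5.25 from embryo to larva and -4.70 from larva to pupa. With KEGG names, which widen the lists, muscle genes stood at 0.15 from embryo to larva and 0.50 from pupa to adult, and from pupa to adult DNA methylation genes stood at -0.20, histone modification at -0.36 and photoreception at 0.23.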

Other observations

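The gene groups in the next 2 paragraphs were chosen after their values were seen. Among the tests on patterns, those on abundant larval genes, on a shift shared by most genes, on sensory cilia and on sperm cells were chosen only after the result was seen.

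Of 8 genes of the Osiris family, 5 were at least 2-fold lower in the larva than in the embryo, with a median of -4.12. From larva to pupa 3 of the 8 were higher and 2 lower, with a median of -0.06. All 7 that could be tested were lower in the adult than in the pupa, with a median of -5.24. Osiris TC012679 stood at 1092 RPKM in the embryo, 13.7 in the larva, 1608 in the pupa and 4.61 in the adult, whereas osiris 7 (TC011660) stood at 2544, 209, 139 and 2.71. UDP-glucuronosyltransferases, which attach sugars to foreign compounds, had medians of 2.42, -1.47 and 1.18 at the 3 steps. Serpins, inhibitors of serine proteases, were higher in the larva than in the embryo in 14 of 23 genes and lower in 4.

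Citric acid cycle enzymes were higher in the adult than in the pupa in 16 of 25 genes and lower in 0, with a median of 1.47. Both other scalings gave larger medians, 1.74 and 1.55. They raise adult values relative to pupal ones, so they do not test this direction. Mitochondrial ribosomal proteins had a median of 0.50 at that step, and 3 of 27 were at least 2-fold higher. Splicing factors were lower in the larva than in the embryo in 57 of 106 genes, with a median of -1.02, or -0.38 after median-ratio rescaling. Proteasome subunits had medians of 0.03, -0.27 and -0.50 at the 3 steps, and 0.69, -0.73 and -0.23 after median-ratio rescaling.

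The embryo and pupal libraries were the most alike of the 6 pairs. Unequal depth is argued against, since the embryo and pupa correlation exceeded the next pair by 0.0992 after thinning to equal reads, and so is counting noise among weak genes, since the gap was 0.153 among genes with a mean of at least 20 RPKM. Leaving out 516 feeding and detoxification genes kept 0.849 of the gap between the embryo and pupa and the embryo and larva correlations, and 0.738 of the gap to the next pair, which was then 0.0729, so these genes are not the whole cause. Other biology shared by these non-feeding stages stays open and was not tested.

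Ribosomal protein genes were lower in the larval library than in the embryo library. A few abundant larval genes are not the whole cause, since the median was -0.83 with the 20 most abundant genes left out of the totals. A shift shared by most genes removes more of it but not all, since the median was -0.45 after median-ratio rescaling, with 57 of 59 genes below 0 and an interquartile range from -0.54 to -0.36. Short gene models are argued against by a percentile of 0.25 among random lists matched on model length. A difference between stages stays open and was not tested, as was a difference between the library preparations.

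Axonemal genes were higher in the adult library. Of 29 genes with a testis or axoneme name in the KEGG field alone, 28 could be tested, and their median from pupa to adult was 1.98, at percentile 99.98, with 18 higher and 2 lower. However, 24 of them have an axonemal but no testis name and would come out alike with any motile cilia. Some of these carry another name as well. TC007515, also named cortactin, stood at 175 RPKM in the pupa and 125 in the adult. TC030610, also named Rad and Gem related GTP binding protein 1, stood at 30.3 and 8.61. The 4 with a testis name are kinases. The testis-specific serine kinase TC007244 stood at 6.00 RPKM in the pupa and 71.4 in the adult, TC009447 at 15.0 and 304, and TC010125 at 8.02 and 135. The other, TC012191, is named testis-specific kinase 2 and also dual-specificity kinase. It stood at 33.1 RPKM in the embryo, 21.2 in the larva, 35.0 in the pupa and 30.2 in the adult. Sperm cells and motile sensory cilia cannot be told apart by these tests. Only these 4 of the genes named in the KEGG field alone carry a testis name. Only 2 intraflagellar transport genes, with a median of 0.17, bear on sensory cilia. The sources used here do not give the number or sex of the adults in this library, and some models may be pieces of 1 dynein heavy chain.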
